A study of Homo sapiens with 12 samples.

How the data were processed

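Ribosome profiling sequences the mRNA fragments that translating ribosomes protect from nuclease digestion, so the number of footprints on a gene reports how many ribosomes it carried. The labels describe 12 samples of HEK293, an established human embryonic kidney cell line, either wild type or with a CRISPR-Cas9 knockout of CNBP. Cells had received cycloheximide, which stalls elongating ribosomes, or harringtonine and cycloheximide, where harringtonine stops newly initiating ribosomes while those already elongating can run off. The labels give 5 wild-type and 3 knockout samples with cycloheximide, and 3 wild-type and 1 knockout samples with harringtonine. Nothing in the labels says that samples of a group came from separate cultures. Both knockout columns carry the same knockout name in their headers, and the number of clones is not given in the sources used here. Differences between clones therefore cannot be told apart from effects of the knockout.

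The authors deposited 1 table of 19219 gene rows with 1 mean per group and no value per sample. Per the file headers it holds average ribosome densities for the 4 groups, log ratios named LFC and values named TE. Per the submitters' processing notes, reads were aligned with TopHat to hg19. The counting tool and annotation are not given in the sources used here. The density unit is the authors' deposited signal per gene, and its values fit reads divided by the listed transcript length and multiplied by a factor per library. The absolute scale of that factor is not stated, so densities are used only in relation to each other. The listed length is that of the longest transcript, not the coding length. The authors' deposited LFC and TE columns are in log2, as their values show, and are entered as a score because spreadsheet error cells stand among the numbers. For the same reason the knockout densities are entered as another kind of value, although they are the same deposited signal as the wild-type ones. Apart from 175 rows set aside below, the LFC column equals log2 of wild type over knockout. With cycloheximide it holds 13432 numbers, beside 4497 division errors and 372 number errors. All ratios given as knockout over wild type have the opposite sign to the deposited columns. The header does not expand TE, and no matched RNA data were used here.

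Before ratios were taken, 918 rows without a knockout value, 290 rows on alternate or patch sequences and 175 rows whose LFC differed from the ratio of the means by more than 1e-06 were set aside (some rows fall under more than 1 of these). Of the usable genes, 12091 had all 4 means above 0, and the 6045 above their median level, a density of 0.114, were compared. The level is the geometric mean of the densities of all 4 groups. Ratios were log2 of 1 authors' mean over another, without a pseudocount, minus the median over the 6045 genes. Those medians were -0.44 for knockout over wild type with cycloheximide, -0.28 with harringtonine, 0.11 for harringtonine over cycloheximide in wild type and 0.27 in the knockout. A gene is called higher or lower when its relative ratio is at least 2-fold. With only group means there is no spread between replicates, so no test between groups was run, no standard deviation between replicates exists and nothing is said to have changed. The design fixed before the data were examined provided for this case by describing values and ratios.

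Depth was estimated from the table itself. At low densities the product of density and length falls on whole multiples of a few steps. The search, with a tolerance of 0.005, stopped at the number of libraries in the labels, and found 5, 3, 3 and 1 steps. Their number could not exceed the labels, so it is no check of them. Of 15, 14, 12 and 2 repeated low products, which include the steps, 0 were unexplained at a wider tolerance. With 2 products this says little about the knockout with harringtonine. The deepest library of a group was 2.76, 2.75 and 2.51 times as deep as the shallowest in wild type with cycloheximide, knockout with cycloheximide and wild type with harringtonine. Dividing the product of density and length by the mean step gave effective reads per gene. Intervals of a ratio are 95% Clopper-Pearson intervals on those effective reads. They cover counting error only, since reads without molecular identifiers are not independent molecules and the replicate spread is unknown. Interaction intervals add the counting errors of both ratios as a normal approximation.

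Gene lists and the rule for named genes were fixed before the data were examined. The rule names CNBP, the 10 largest ratios each way for the cycloheximide comparison and for the drug in wild type, the 5 largest each way for the other 2 comparisons, and up to 3 members of each list. The rule ranked list members by p, which does not exist here, so they were ranked by the size of the ratio over its counting error. Of the 26 lists, 23 had at least 5 members among the genes compared. The median of a list was placed among 10000 random lists of the same size matched on level decile, as a description of these libraries and not as a test. A list outside the central 95% is called outside.

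The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The ratios and intervals were tested on simulated data with the real genes and steps, with the wild-type cycloheximide means as the starting densities of all groups. For the cycloheximide comparison (6045 genes) the intervals covered the true ratio for 96.7% of genes, and 1.01% of unchanged genes came out beyond 2-fold by counting alone. There, 44% of genes made 2-fold different and 98% of genes made 4-fold different passed the 2-fold bound. For the harringtonine comparison (6037 genes) coverage was 96.3% and 5.64% of unchanged genes came out beyond 2-fold. The placing of lists was tested on normally distributed values in place of the real genes. Of 200 random lists 5.5% fell outside, and 20 of 20 lists shifted by a whole SD did. How often a smaller shift would be found was not tested.

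Choices made after the data were seen are the effective reads and their intervals, the centring on the median, the sets of genes with at least 100 effective reads, the row filters, the ranking of list members, the genes named for differing in both treatments, the genes left out for a 0 but placed in a ranking, and all alternatives for the gene lists. The alternatives tried were pseudocounts of 0.1, 1 and 5, no level filter, arithmetic mean densities of at least 1 and 10, and upper-quartile scaling. Also tried were the deposited scale without centring and genes with at least 100 effective reads. For the lists, the alternatives were matching on length and keeping genes listed at 0. In the last, a 0 was set to 3 effective reads, and a gene entered a comparison unless both groups lay at or under that floor. Genes on the mitochondrial chromosome stayed in. Genes with near-identical copies (the MTRNR2L, NPIP, histone and RGPD families, HBA1) are uncertain, because the handling of reads that fit several places is not given in the sources used here. The G-rich elements that CNBP binds were not analysed here, since that needs a genome sequence. Some members of the lists are not reported here.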

Results

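The table measured ribosome footprints per gene in HEK293 cells, wild type or labelled as a knockout of CNBP. This zinc-finger protein binds G-rich stretches of mRNA. The series asks whether the loss of CNBP alters translation of its target mRNAs. It averages 5 wild-type and 3 knockout libraries with cycloheximide, and 3 wild-type libraries and 1 knockout library with harringtonine and cycloheximide. The table gave an estimated 2157985 effective reads for wild type with cycloheximide, 866149 for the knockout with cycloheximide, 1139543 for wild type with harringtonine and 406300 for the knockout with harringtonine. The median of the 6045 genes compared had 96.0, 33.3, 37.5 and 16.5 effective reads in the same order. C16orf93 alone took 10.7%, 14.6%, 16.4% and 14.0% of them, and the MTRNR2L family, copies of a mitochondrial ribosomal RNA segment, 21.3%, 26.7%, 11.0% and 22.4%. Only a mean per group was used, so all intervals below are 95% counting intervals and leave out the spread between replicates. All log2 ratios are relative to the median of the genes compared.

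Footprints on CNBP itself were lower but present in the knockout. CNBP (ENSG00000169714, hg19 chromosome 3, 128888327 to 128902765, minus strand) had an authors' mean density of 3.73 in wild type and 2.20 in the knockout with cycloheximide, and of 3.27 and 2.36 with harringtonine. Its relative log2 ratio of knockout over wild type was -0.32 with cycloheximide (interval -0.58 to -0.07), where 26.6% of genes were lower still, and -0.19 with harringtonine (interval -0.59 to 0.20), where 37.7% were lower. On the deposited scale, without centring on the median gene, the cycloheximide value was -0.76. In the authors' deposited table CNBP has an LFC, wild type over knockout, of 0.76 with cycloheximide and 0.47 with harringtonine. These values rest on 637 and 165 effective reads with cycloheximide and on 198 and 74 with harringtonine. A whole-gene footprint value neither shows nor excludes small insertions or deletions of the kind Cas9 makes, so it checks the knockout labels only weakly.

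With cycloheximide, TRPV2, a calcium-permeable channel, had the largest knockout ratio of the 6045 genes, with a log2 ratio of 6.94 (interval 5.70 to 8.58), from 5 to 199 effective reads. SSH1, a phosphatase that activates the actin-severing protein cofilin, followed at 3.79 (3.69 to 3.88), METTL24 at 3.75, WBSCR17, a glycosyltransferase of the GalNAc-transferase family, at 3.66 and METRNL, a secreted meteorin-like factor, at 3.32. C11orf95 (3.11), HMHA1 (2.98), MTHFSD (2.72), COMMD2 (2.68) and GATAD2A (2.62), a subunit of the NuRD chromatin complex, completed the 10 largest. With harringtonine the deposited LFC, wild type over knockout, put most of these on the lower side. It was 1.30 for TRPV2, 0.64 for SSH1, 0.39 for METTL24, 1.49 for WBSCR17 and 3.08 for METRNL. For C11orf95, MTHFSD and GATAD2A it was 0.77, 1.34 and 3.27, whereas HMHA1 (-0.66) and COMMD2 (-3.72) stayed on the higher side. Further well-counted genes on the higher side were TMC5 (2.55), NEURL1 (2.28), METRN (1.84), the lysosomal protease CTSA (1.77) and the iron transporter SLC11A2 (1.68).

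Among the 6045 genes, which have all 4 means above 0, the lowest ratio with cycloheximide was that of TMEM126A, needed for the assembly of mitochondrial complex I, at -3.38 (interval -9.22 to -0.69), NIPSNAP3A at -2.85 and SCO2, a copper chaperone of cytochrome c oxidase, at -2.79 (-4.97 to -1.24). MT-ND6, the complex I subunit encoded on the light strand of mitochondrial DNA, was -2.52 (-2.77 to -2.28), with authors' means of 49.2 in wild type and 6.31 in the knockout. The cargo receptor TMED1 (-2.80), KTI12 (-2.70), SUMO4 (-2.46) and ALG1L (-2.33, interval -6.90 to 0.14) were also among the 10 lowest, as were NPIPA3 (-2.62) and NPIPA8 (-2.55), whose near-identical copies make them uncertain. A pair of genes left out only because the knockout with harringtonine is listed at 0 would rank with these, SAA1, an acute-phase protein, at -4.23 (interval -5.70 to -3.08) and MT-CO2, of cytochrome c oxidase, at -2.87 (-3.30 to -2.48). With harringtonine the deposited LFC put SCO2 (-2.34), SUMO4 (-0.88), MT-ND6 (-0.72), KTI12 (-0.64) and NPIPA3 (-0.040) higher in the knockout. It put ALG1L (2.41), TMED1 (1.28), TMEM126A (0.67), NPIPA8 (0.12) and NIPSNAP3A (0.074) lower. That LFC is not centred, and its median over the genes compared was 0.28. Relative to the median gene, NPIPA8 (0.17) and NIPSNAP3A were therefore higher in the knockout with harringtonine. Among well-counted genes, NDUFS7 of complex I was -1.08 (-1.23 to -0.93), the mitochondrial pore VDAC1 -0.90, the mitotic cyclin CCNB1 -0.86 and the mitochondrial chaperone HSPD1 -0.83. In all, 268 genes were at least 2-fold higher and 196 at least 2-fold lower of 6045, and for 255 and 168 of them the interval excluded 0. Among 694 genes with at least 100 effective reads in both groups, 37 were higher and 3 lower. The split depends on the centring: without it 59 were higher and 844 lower, and with upper-quartile scaling 184 and 274. Above a mean density of 1 the split was 47 and 3, relative to the median of the genes kept. With a pseudocount of 1 it was 9 and 3.

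Of the 23 gene lists, 3 lay outside the random lists with cycloheximide, where 1.15 would for genes drawn at random. Members of a list can move together between libraries, so that count does not gauge differences between libraries. The 18 integrated stress response targets had a median of -0.36 (percentile 1.72), with 12 below the all-gene median and 6 above. Among them PSAT1, of serine synthesis, was -1.07 (interval -1.49 to -0.66) and asparagine synthetase ASNS -0.85 (-1.25 to -0.48), whereas PPP1R15A, which reverses eIF2 phosphorylation, was 1.21 (0.31 to 2.08). Matched on transcript length as well, this list moved inside (percentile 3.11). The 20 glycolysis and hypoxia genes had a median of -0.35 (percentile 2.34), 17 of them below, including ENO1 (-0.60), LDHB (-0.48) and GAPDH (-0.30). Above a mean density of 1 their percentile was 9.06 and inside. Mitochondrially encoded genes went both ways and their call does not hold. The 6 with all 4 means above 0 had a median of 0.36 (percentile 99.5) and a mean of -0.03, with MT-ND4 at 1.07 and MT-ND5 at 0.79. Another 4, left out because the knockout with harringtonine is listed at 0, were lower with cycloheximide, MT-CO2 at -2.87, MT-CO1 at -2.13, MT-ND2 at -1.08 and MT-ND1 at -0.27. With all 10 the median was -0.24 and inside (percentile 38.1). On the deposited scale every log2 ratio here is 0.44 lower.

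The translation machinery was mostly below the all-gene median with cycloheximide, as were other highly translated genes. Of 76 cytosolic ribosomal protein genes, 61 were below, with a median of -0.20 and examples RPL9 (-0.60), RPS4X (-0.53) and RPS24 (-0.47), yet among random lists of similar level they ranked at percentile 69.4. The 20 translation factors and other mRNAs with a 5' terminal oligopyrimidine tract had a median of -0.30 (percentile 11.4), with EEF1A1 at -0.47 and GNB2L1 at -0.73. Of 19 aminoacyl-tRNA synthetases, 17 were below (median -0.37, percentile 3.30), such as FARSB (-0.80) and IARS (-0.62), with HARS at 0.79. The 30 helicases and binding proteins of G-rich or structured RNA had a median of -0.24 (percentile 11.6), 25 of them below, including HNRNPH1 (-0.74) and DDX21 (-0.67). Initiation factors had a median of -0.10, with EIF2S1 at -0.90 and EIF3J at -0.76, and ribosome biogenesis genes -0.27 (percentile 5.29), with the pseudouridine synthase DKC1 at -0.86.

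Genes earlier linked to CNBP were inside the random lists. Of 5 measured, 4 were below the all-gene median, and their median was -0.27 (percentile 27.7). MYC was -0.64 (interval -0.97 to -0.32), the cyclin CCND1 -1.14 (-1.96 to -0.40) and HNRNPK -0.27 (-0.43 to -0.12). The proteasome (median -0.28, PSMB6 -1.09, PSMD1 -0.92), nuclear-encoded oxidative phosphorylation (-0.24, ATP5B -0.59), sterol synthesis (-0.18, ACLY -0.56), heat-shock (-0.34, HSPA8 -0.59), spliceosome (-0.28, SNRPE -0.89), DNA replication (-0.21, PCNA -0.40) and double-strand break repair lists (-0.28, PRKDC -0.55) were inside too. So were the endoplasmic reticulum chaperones (-0.13, MANF 0.91, PDIA6 -0.62), mitotic genes (-0.08, BIRC5 0.96), histones (-0.02, HIST1H2AC 0.46), p53 targets (0.23, XPC -1.31), interferon-stimulated genes (0.14, IRF9 0.68) and epithelial markers (0.23, KRT19 1.70). The interferon list's mean was below 0, and the p53, interferon, epithelial and matrix medians are below 0 on the deposited scale. Matrix, neuronal and haematopoietic markers had 4, 4 and 2 measured members, too few to rank, with medians of 0.18, -0.23 and 0.76.

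**Figure D1:**
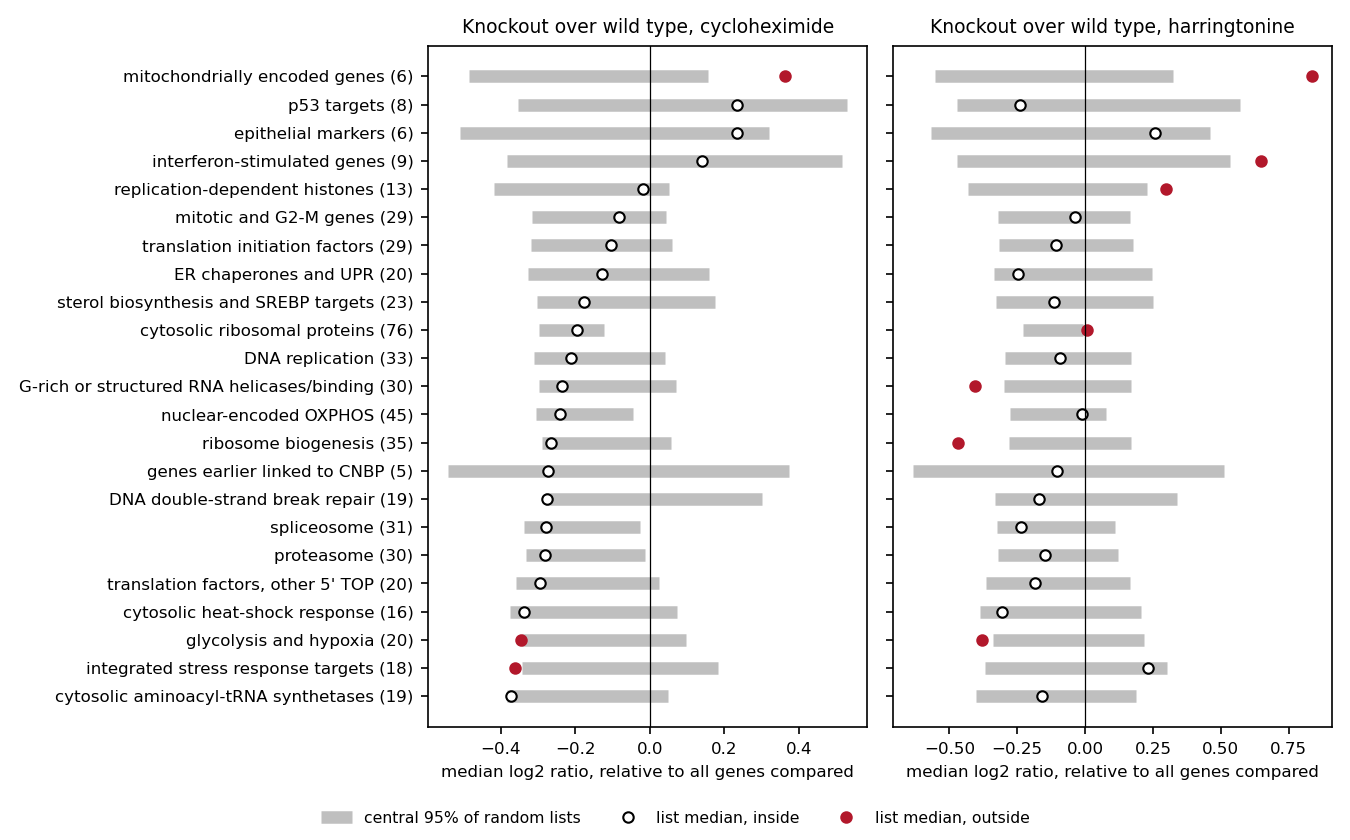
Median log2 ratio of knockout over wild type, relative to the median of all genes compared, for each gene list (rows, with measured members in parentheses), with cycloheximide on the left and harringtonine on the right. Points are list medians, filled where outside the grey bars, which span the central 95% of random lists of similar level; with cycloheximide the stress response list lies at -0.36, and mitochondrially encoded genes at 0.36 for the 6 members plotted but at -0.24 with all 10, and the harringtonine panel also leaves out the 4 listed at 0.

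The knockout ratio was lower for genes with more footprints. With cycloheximide the median log2 ratio on the deposited scale was -0.28 in the decile of genes with the fewest footprints and -0.67 in the decile with the most. With harringtonine these medians were -0.19 and -0.41. Across genes, which are not independent replicates, level and the knockout ratio had a Spearman rho of -0.21 with cycloheximide and -0.11 with harringtonine. Among the 321 genes with at least 100 effective reads in all 4 groups the cycloheximide value was 0.10.

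**Figure D2:**
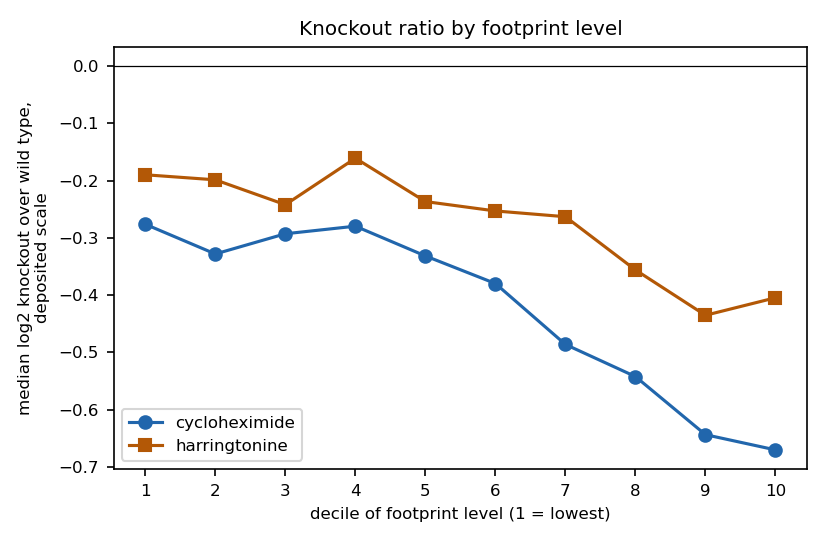
Median log2 ratio of knockout over wild type on the deposited scale (vertical axis) by decile of footprint level, from lowest to highest (horizontal axis), for the 6045 genes compared. Circles are cycloheximide, from -0.28 to -0.67, and squares harringtonine, from -0.19 to -0.41.

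With harringtonine, which enriches ribosomes at start sites, the single knockout library had its highest ratios over wild type at TSPEAR (log2 ratio 10.19, interval 7.68 to 15.57, where wild type has 1 effective read), COMMD2 (4.01), the stress factor DDIT3 (3.81, interval 1.13 to 8.27), MCHR1 (2.94) and OASL, an interferon-induced gene (2.92). Among genes with all 4 means above 0, the lowest ratios were those of VSTM2A (-4.99), mitochondrial PEP carboxykinase PCK2 (-4.65), HINT2 (-3.63), CYHR1 (-3.59) and the homeobox gene EN1 (-3.56). Among well-counted genes CDK6, a G1 cyclin-dependent kinase, was -3.55, ARSI -3.35 and METRNL -2.79, whereas ZKSCAN1 was 1.49, LTA4H, of leukotriene synthesis, 1.30 and CDK5R1 1.28. In wild type, CDK6, ARSI and METRNL had authors' means of 2.07, 35.6 and 4.81 with cycloheximide and 62.2, 193 and 66.5 with harringtonine. In the knockout they had 3.45, 80.9 and 35.3 with cycloheximide, each above wild type, and 4.34, 15.6 and 7.88 with harringtonine. The MTRNR2L5 value of 1.56 is uncertain because of near copies. In total 406 genes were at least 2-fold higher and 398 lower, and the interval excluded 0 for 259 and 254. The split was 5 and 25 with a pseudocount of 1, 2 and 12 with a pseudocount of 5, 10 and 16 among 322 genes with at least 100 effective reads in both groups, and 190 and 757 without centring. Counting alone puts 5.64% of unchanged genes beyond 2-fold at this depth, and a single knockout library gives no replicate check.

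In the same comparison 7 of 23 lists lay outside, of which the mitochondrially encoded genes are not read as a direction, since a 0 in this comparison decides which members enter. The 6 that entered were above the all-gene median (median 0.84), such as MT-ND6 (1.00) and MT-CO3 (0.39). The other 4 are listed at 0 in the knockout, where wild type has authors' means of 127 for MT-CO1, 10.1 for MT-CO2, 1.33 for MT-ND2 and 0.944 for MT-ND1, and no fold against a 0 is given. Above were interferon-stimulated genes (0.65, 8 of 9, percentile 99.1), histones (0.30, 9 of 13, percentile 99.0) and ribosomal proteins (0.01, 38 of 76, percentile 98.5, with a mean just below 0). Below were the helicases and binding proteins of G-rich or structured RNA (-0.41, 26 of 30 below, percentile 0.26), ribosome biogenesis (-0.47, 28 of 35, percentile 0.02) and glycolysis and hypoxia (-0.38, 15 of 20, percentile 1.41). Matched on transcript length as well, ribosomal proteins (percentile 90.5), histones (82.5) and interferon-stimulated genes (96.7) moved inside. Stress response targets, low with cycloheximide, had a median of 0.23 here (percentile 94.4), which is -0.05 on the deposited scale. The ribosomal protein median is below 0 on that scale and after upper-quartile scaling.

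Some genes differed by at least 2-fold in the same direction with both treatments, a comparison of 4 separate sets of libraries. CTSA was 1.77 with cycloheximide and 2.18 with harringtonine, COMMD2 2.68 and 4.01, SLC11A2 1.68 and 1.83, the actin-binding COTL1 1.41 and 1.87, the keratins KRT19 1.70 and 2.12 and KRT10 2.23 and 1.63, and the transcription factor TFAP2B 2.61 and 1.33. On the lower side CCND1 was -1.14 and -3.01, NDUFS7 -1.08 and -1.58, the mitochondrial elongation factor TSFM -1.19 and -1.40, the carbonic anhydrase CA2 -1.32 and -1.11 and TCEA1, a transcription elongation factor, -1.16 and -1.36. There were 43 such genes on the higher side, where 18.0 would be shared by independent lists, and 20 on the lower side, where 12.9 would; both intervals excluded 0 for 28 and 10. In opposite directions, 34 genes were higher with cycloheximide and lower with harringtonine (17.6 for independent lists) and 23 the reverse (13.2), so opposite calls exceeded that count as well. These genes were named after their values were seen. Across all 6045 genes the ratios of the 2 treatments had a Pearson r of 0.11 and a Spearman rho of 0.15, and lay on the same side for 56.8% of genes. Among the 321 genes with at least 100 effective reads in all groups r was -0.17 and rho 0.10.

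**Figure D3:**
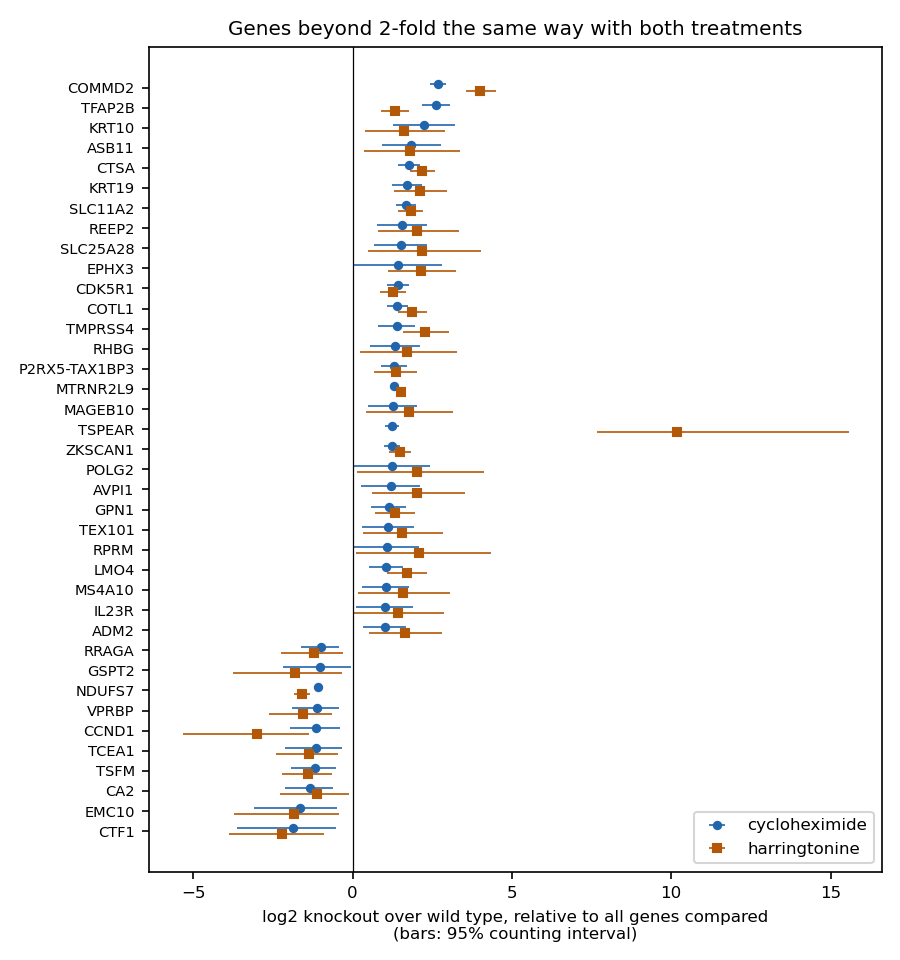
Relative log2 ratio of knockout over wild type for the genes at least 2-fold higher (28) or lower (10) with both treatments whose intervals both exclude 0, a gene per row, with cycloheximide and harringtonine as separate points and 95% counting intervals as bars. COMMD2 lies at 2.68 and 4.01, and CCND1 at -1.14 and -3.01.

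The difference between the knockout ratios of the 2 treatments, the interaction, was largest for TSPEAR (log2 8.94, interval 6.07 to 11.80), SCO2 (5.40), the pyruvate dehydrogenase kinase PDK3 (5.04), DDIT3 (4.43) and PPP1R35 (3.86), where the harringtonine ratio was the higher one. It was lowest for TRPV2 (-7.97, interval -10.02 to -5.92), METRNL (-6.12), GATAD2A (-5.61), FAM47E-STBD1 (-5.22) and CYHR1 (-5.01). CNBP stood at 0.12 (interval -0.34 to 0.58). In total 559 genes were at least 2-fold higher and 656 lower, and the interval excluded 0 for 348 and 370. How many unchanged genes counting alone would put beyond 2-fold was not simulated for the interaction. Its median counting error in log2 was 0.53, against 0.29 and 0.43 for the knockout ratios with cycloheximide and harringtonine. The split was 779 and 480 without centring, but 14 and 40 with a pseudocount of 1 and 6 and 27 among the 321 genes with at least 100 effective reads in all groups, relative to their own median.

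Harringtonine in wild type gave large ratios over cycloheximide alone at CYHR1 (log2 5.12), CDK6 (4.80, interval 4.74 to 4.86, authors' means of 2.07 and 62.2), EN1 (4.44), PPP1R3E (3.97), METRNL (3.68), the homeobox gene HOXB8 (3.32), METRN (3.27), TRPV2 (3.23), BMP8B (3.20) and TULP1 (3.19). In the knockout CDK6 had authors' means of 3.45 with cycloheximide and 4.34 with harringtonine. Among the genes compared the lowest ratios were those of TSPEAR (-7.14, from 361 to 1 effective reads), the cytochrome c oxidase assembly gene COX14 (-3.23), HAUS4 of the augmin complex (-3.02), DDIT3 (-2.82), interferon-induced IFI6 (-2.67), the uncoupling protein UCP2 (-2.64), IMP4 (-2.23), TRAPPC6A (-2.20), URM1 (-2.15) and the histone demethylase KDM6B (-2.12). SAA1, left out because the knockout with harringtonine is listed at 0, would rank with these at -3.30. Well-counted genes on the lower side included MT-CO3 (-1.32), MT-ND6 (-1.22) and the transport receptor TNPO2 (-1.21). In total 206 genes were at least 2-fold higher and 200 lower, with the interval excluding 0 for 199 and 173. Among 1015 genes with at least 100 effective reads in both groups, 64 were higher and 7 lower. The split was 270 and 135 without centring, 38 and 4 with a pseudocount of 1 and 22 and 0 with a pseudocount of 5.

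Lists at both ends stood apart with harringtonine in wild type. Ribosomal protein genes were lower (median -0.23, 58 of 76 below, percentile 0.01), with RPL27 at -0.64, RPS15 at -0.60 and RPS10 at 1.16. Mitochondrially encoded genes were lower too (-0.79, 8 of 10, percentile 0, with those listed at 0 in the knockout kept, and -1.06 without these), although MT-CO1 was 0.65 and MT-ND2 0.22. Lower as well were histones (-0.43, 12 of 13, percentile 0.25), with HIST1H2BK at -0.77, nuclear-encoded oxidative phosphorylation (-0.20, 30 of 45, percentile 0.29), with COX7C at -0.74, and interferon-stimulated genes (-0.60, 5 of 9, percentile 0.16), with OASL at -1.49. Higher were the helicases and binding proteins of G-rich or structured RNA (0.39, 27 of 30 above, percentile 100), such as NCL (0.66), ribosome biogenesis (0.28, 28 of 35, percentile 99.6), with MYBBP1A at 0.86, and endoplasmic reticulum chaperones (0.30, 18 of 20, percentile 98.7), with CALR at 0.56 and CANX at 0.48. Matched on transcript length as well, histones (percentile 5.75), oxidative phosphorylation (5.00) and chaperones (96.4) moved inside. Above a mean density of 1 ribosome biogenesis did (66.0), and without a level filter the chaperones did (96.6). Stress response targets (median -0.22), inside when matched on level alone (percentile 4.18), moved outside below when matched on length as well (1.76).

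In the knockout the drug ratio was again low for ribosomal proteins (median -0.04, 44 of 76 below, percentile 0.38, mean 0.0032), mitochondrially encoded genes (-0.62, 5 of 6, percentile 0.07) and histones (-0.28, 9 of 13, percentile 0.27). The mitochondrially encoded value leaves out the 4 genes listed at 0 in the knockout with harringtonine. On the deposited scale, where every ratio is 0.27 higher, the ribosomal protein median is 0.24, and it is above 0 after upper-quartile scaling too. Aminoacyl-tRNA synthetases (0.40, 16 of 19 above, percentile 98.9) and stress response targets (0.36, 14 of 18, percentile 98.2) were higher, while the G-rich RNA binding list was inside (0.22, percentile 91.7). Matched on transcript length as well, histones (percentile 4.79) and stress response targets (97.3) moved inside. Whether the drug ratios of the genotypes differ for a list was not tested. The drug ratio in wild type and the harringtonine knockout ratio use the same wild-type harringtonine libraries on opposite sides. Opposite results of a gene or list in these 2 comparisons are therefore in part built in. The same holds for the knockout cycloheximide libraries, which enter the cycloheximide knockout ratio and, on the opposite side, the drug ratio in the knockout, where stress response targets and aminoacyl-tRNA synthetases were low and high.

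**Figure D4:**
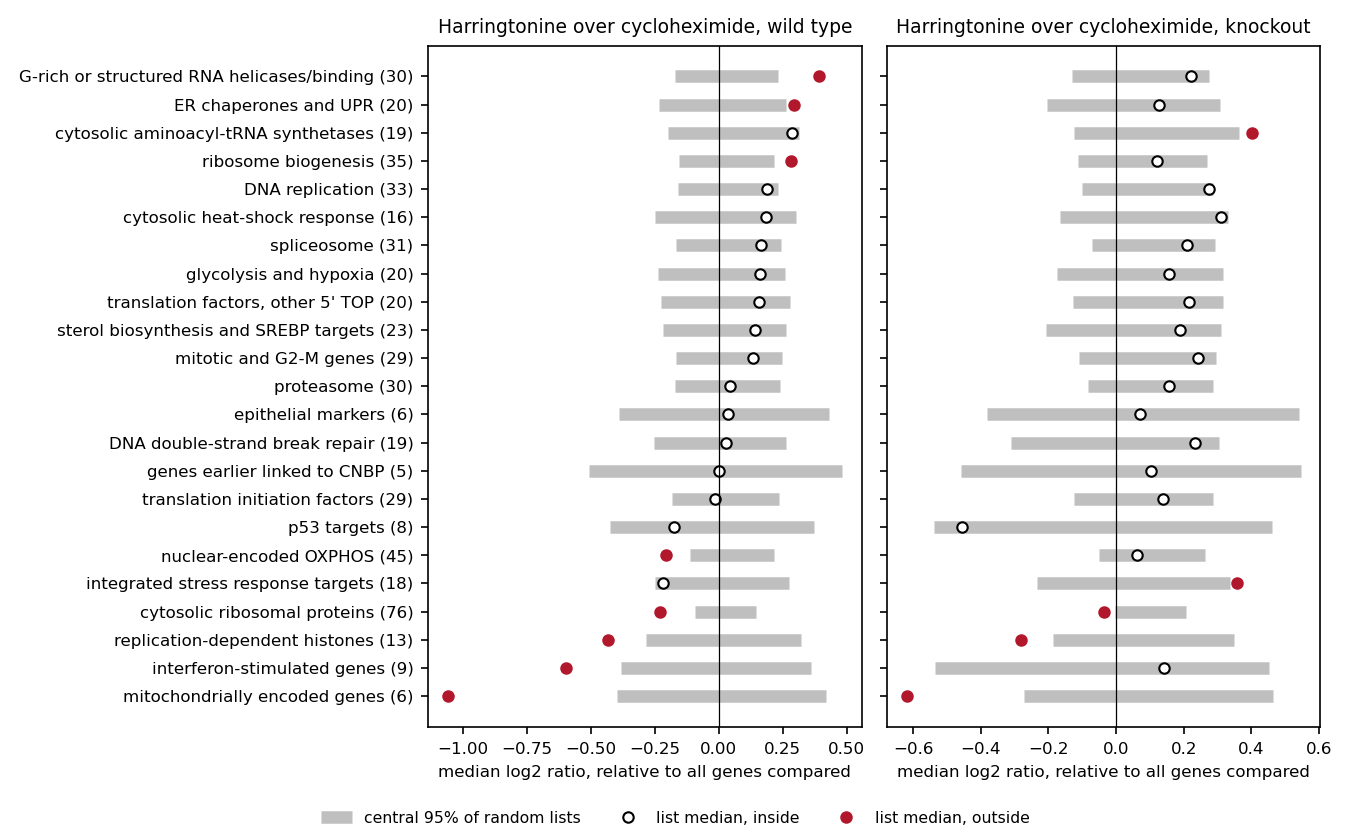
Median log2 ratio of harringtonine over cycloheximide alone, relative to the median of all genes compared, for each gene list (rows, with measured members in parentheses), in wild type on the left and in the knockout, 1 harringtonine library over the mean of 3 cycloheximide libraries, on the right. Points are list medians, filled where outside the grey bars, which span the central 95% of random lists of similar level; mitochondrially encoded genes lie lowest, at -1.06 and -0.62 for the 6 members with all means above 0.

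The authors' deposited table also gives a TE value, read here as a log2 ratio with footprints set against another measurement, which the header does not name. For CNBP the authors' deposited table has TE values, wild type over knockout, of 0.85 with cycloheximide and 0.56 with harringtonine. Turned to knockout over wild type and centred, TE from the authors' deposited table was at least 2-fold higher for 345 genes and lower for 233 with cycloheximide. The split was 231 and 318 after upper-quartile scaling, 100 and 918 without centring, and 30 and 22 with a pseudocount of 1. Among the 697 genes with at least 100 effective reads in both groups, relative to their own median, the split was 57 and 4. In the centred TE of all 6045 genes compared, stress response targets (median -0.50, 13 of 18 below, percentile 0.07), the proteasome (-0.38, percentile 1.16) and ribosome biogenesis (-0.33, percentile 1.43) were outside below. Epithelial markers (0.41, percentile 98.5) were outside above. Mitochondrially encoded genes were above with 6 members (0.63, percentile 99.9) and inside with 10 (0.079, percentile 97.0). Without centring, the epithelial median is -0.042. Turned this way, TE is the footprint ratio minus the amount TE minus LFC. That amount has a list median of 0.33 for stress response targets, so their low TE in part reflects it.

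TE minus LFC in the authors' deposited table was 1 amount per gene, the same with both treatments to within 1.33e-15. It was exactly 0 for 326 of the 13432 rows with a number, where TE adds nothing to LFC. The header does not say what this amount is. Its sign is that of knockout over wild type if TE sets footprints against mRNA. This amount had an SD over genes of 0.22, and 15 genes were at least 2-fold higher and 20 lower. For 17 of 18 stress response targets it was above the all-gene median (list median 0.33, percentile 100), among them DDIT3 (0.80), DDIT4 (0.71), SESN2 (0.56), PPP1R15A (0.55), ATF5 (0.47), ASNS (0.40) and ATF4 (0.23). Ribosomal proteins (0.11, 60 of 76 above, percentile 100), mitotic genes (0.09, 23 of 29, percentile 99.1) and heat-shock genes (0.11, 13 of 16, percentile 98.8) were above as well. Mitochondrially encoded genes (-0.29, 10 of 10 below, percentile 0) and epithelial markers (-0.16, 5 of 6, percentile 1.47) were below. The amount for CNBP was 0.079.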

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

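All settings without centring or with at least 100 effective reads, all settings for the gene lists and all for the comparison between treatments were chosen after the results were seen. No paired analysis was possible because the table holds only group means. For the same reason the count-model tests and their other normalizations, the limma fits, leaving out replicates, a shared spread, a minimum fold test and the set tests with other correlations were not run. Alternatives on categories were not run, as no such column was used, nor was a level filter on both assays of TE. Totals of genes beyond 2-fold are given for knockout over wild type with cycloheximide (464 as reported), the drug in wild type (406), knockout over wild type with harringtonine (804), the interaction (1215) and TE (578), in that order. With a pseudocount of 0.1 they were 105, 175, 296, 488 and 209, with 1 they were 12, 42, 30, 54 and 52, and with 5 they were 4, 22, 14, 21 and 38. A pseudocount above most densities shrinks low genes by construction. Without a level filter they were 1968, 1744, 2916, 3835 and 2242 of 12091 genes. With a mean of at least 1 (721 genes) they were 50, 68, 58, 86 and 53, and with at least 10 (59 genes) 8, 15, 12, 11 and 8. With at least 100 effective reads they were 52, 61, 27, 33 and 61. In this and the other settings that change which genes are kept, the median is that of the genes kept. Upper-quartile scaling kept all 5 totals within 1.5 times. Without centring the totals were 903, 405, 947, 1259 and 1018, and CNBP with cycloheximide was -0.76 in place of -0.32. Under the other settings CNBP ranged from -0.48 to -0.09. The Spearman rho between treatments, 0.15, was 0.20, 0.30 and 0.33 with the pseudocounts, 0.12 without a filter, 0.019 with a mean of at least 1, -0.030 with at least 10 and 0.10 with at least 100 effective reads; the cause was not tested. HIST1H1E with cycloheximide, 0.27, turned to -0.087 and -0.13 with pseudocounts of 1 and 5 and to -0.18 without centring. Of the other values for named genes, 40, 140 and 197 moved outside their interval with the 3 pseudocounts, 12 with upper-quartile scaling and 92 without centring. The number of lists outside, 3 with cycloheximide and 8 for the drug in wild type, ranged from 2 to 4 and from 6 to 9. Keeping genes listed at 0 moved the mitochondrially encoded list inside with cycloheximide (percentile 38.1 in place of 99.5). Counting error limits the harringtonine comparisons, where the knockout library had a median of 16.5 effective reads per gene.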

Other observations

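Of the values below, the amount of background, the tests of the TE and LFC columns and the matching on transcript length were chosen after the list results or ratios were seen. Several mitochondrially encoded genes are listed at 0. MT-ATP8, MT-ND3 and MT-ND4L are at 0 in both wild-type groups and have no knockout value, and another 4 are at 0 in the knockout with harringtonine alone. MT-CO1 had authors' means of 75.3 in wild type and 12.7 in the knockout with cycloheximide, 127 in wild type with harringtonine, and is listed at 0 in the knockout with harringtonine. MT-CO2 had 17.1, 1.72 and 10.1 and is likewise listed at 0, as are MT-ND1 and MT-ND2, 4 genes that lie side by side between positions 3307 and 8269. Of the 756 genes listed at 0 only in that group, MT-CO1 alone would have had over 100 effective reads at the geometric mean of its densities in the other groups. MT-ND6, encoded on the opposite strand, had an authors' mean of 37.6 there.

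BMP8B and FLYWCH1, on different chromosomes, had nearly equal effective reads in all groups, 19509 and 19190 in wild type and 13195 and 11692 in the knockout with cycloheximide, and 68916 and 66884 in wild type and 6447 and 6367 in the knockout with harringtonine. The 82 genes on chromosome 18 had a median relative log2 knockout ratio of 0.23 with cycloheximide and 0.33 with harringtonine. The 588 genes on chromosome 19 had 0.20 with cycloheximide and -0.034 with harringtonine. Across 23 chromosomes the medians of the 2 treatments had a Spearman rho of -0.23 and a Pearson r of 0.29, so they did not go together in rank. In the amount TE minus LFC of the authors' deposited table, chromosome 21 had a median of -0.22 and chromosome 18 of 0.09. The genes highest in that amount were NPIPA8 (2.18), RGPD1 (2.08) and CD300LD (1.99), the first 2 of which have near copies, and the lowest were BHLHE22 (-2.03), FOXB2 (-2.01) and C1orf95 (-1.72).

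The knockout ratio with cycloheximide was lower for genes with more footprints, by a log2 difference of -0.39 between the top and bottom deciles. Reads of background spread over all genes would raise low genes, and 468 genes of receptor and other families silent in kidney cells had a log2 ratio of -0.062 (interval -0.42 to 0.29) against an all-gene median of -0.44, but their density in the knockout, 0.00288, could lift the lowest decile by at most 0.040, which argues against evenly spread background. Counting noise combined with binning by level gave differences no lower than -0.055 in 100 simulations, which argues against it. An effect of the knockout on highly translated mRNAs, and RNA fragments of expressed genes that did not come from ribosomes, were not tested and stay open.

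The amount TE minus LFC of the authors' deposited table was unrelated to the footprint ratio (Spearman rho 0.00 with cycloheximide), although mRNA and footprints of a gene would be expected to move together. Neighbouring genes had a rank correlation of 0.14 in that amount, against at most 0.05 in 1000 shuffles, which argues against rows scattered at random. Rows shifted by a few positions or in blocks would keep neighbours alike, so the value cannot decide on these. Counting noise in footprints would leave a slope of about 1, and the slope was 0.04 with an upper bound of 0.42 among 694 well-counted genes, which argues against footprint noise as the whole cause. Noise in the amount itself, which also lowers the slope, buffering of mRNA differences by translation, or RNA from other cultures than those profiled, may also account for it and were not tested.

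Against random lists of similar level, ribosomal proteins, histones and mitochondrially encoded genes were low with harringtonine in both genotypes. Ribosomal proteins in the knockout had a median of only -0.04, a mean of 0.0032 and 44 of 76 below the all-gene median. Oxidative phosphorylation and interferon-stimulated genes, low in wild type, were inside in the knockout (percentiles 27.1 and 77.3). A candidate explanation for ribosomal proteins and histones is that short mRNAs lose their ribosomes sooner. Matched on transcript length, the wild-type percentile was 0.25 for ribosomal proteins and 0 for 6 mitochondrially encoded genes (0.01 for all 10). This argues against listed transcript length alone for these lists. Coding length was not matched, so the values cannot decide whether short coding sequences account for the low ratios of ribosomal proteins and histones. For histones the percentile was 5.75, inside the random lists, so their low value could go with their listed length. In the knockout, matched on length, histones were inside as well (percentile 4.79). A specific response of ribosomal protein and histone mRNAs to harringtonine, and reads shared among histone copies, stay open and were not tested. Chance differences of the few libraries stay open for each of these lists and were not tested either.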
